A study of Mus musculus with 5 samples.

How the data were processed

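RNA-seq was available for 5 libraries of wild-type mouse BMSCs, 1 at each of 0, -80, -120, -160 and -200 mmHg. Cells were cultured for 72 h and the pressure was held for 48 h, per the labels' protocols. The authors deposited 1 table of FPKM values per gene and library. Per the submitters' processing notes, HISAT2, SAMtools and featureCounts 1.5.0-p3 were used with the build rn6, a rat genome. All 55401 gene IDs in the deposited table are mouse Ensembl IDs, and mouse exon lengths turn its values into whole reads, so the mouse annotation was used and the named build was not. Whether reads were counted by strand is not given in the sources used here, so overlapping and antisense genes, and near-identical paralogs, may share reads.

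Gene symbols, exon lengths and biotypes came from GENCODE release M21. Of 55401 IDs 54349 matched with their version and 55141 in any version. The deposited FPKM multiplied by exon length was a whole multiple of 1 step per library in 54719 genes (tolerance 0.001 reads), and the step gave the library totals, from 16600622 to 18398911 reads. The recovered reads made up 98.1% to 98.5% of these totals. They were used for counting intervals, floors, read numbers of single genes, 1 alternative, simulated and redrawn reads, and the cut on Y-linked genes. No count model compared the conditions with them. Intervals of ratios are exact Clopper-Pearson intervals at 95%, and the floor for a gene with 0 reads is 3 reads per library. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Columns of other samples numbered 0.

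Values were compared on the log2(FPKM + 1) scale over the 12113 genes with a mean of at least 1 FPKM over the 5 libraries. With 1 library per condition no single pressure can be tested against the control, and no model that pools the pressures or fits a trend was run, so genes were counted by a fixed rule of size (a log2 difference of at least 1). A gene counted as ordered by pressure when it changed in 1 direction at every step and by at least that size between its lowest and highest library. The number of genes in which the control stood apart was ranked among the 5 choices of a library, and the number of genes ordered by pressure among 60 orders, by exact permutation. For 34 gene lists fixed in advance, the median log2 change of the measured members was placed among 10000 random lists of the same size matched in 20 bins of mean expression. A list stood apart below the 2.5 or above the 97.5 percentile, which describes these libraries and is no test. Lists with under 5 measured members had no percentile.

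Genes were named by a rule written before the data were examined. It took the 10 largest increases and 10 largest decreases at each pressure among genes with at least 5 FPKM in the higher library and a symbol that is not a predicted or clone name, up to 4 members past the size rule in each list, and 18 genes fixed by name. It also took the 5 largest rising and 5 largest falling ordered genes, the 5 largest genes on each side in which the control stood apart, and 3 genes on each side for each pressure library. Y-linked and Hox genes fall outside it, and some genes that it names are not reported here. The file gives no biotype, so the alternative of coding genes only that was fixed in advance was run with GENCODE biotypes and counts as added later.

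The alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 FPKM, a trimmed mean of log ratios (30% trimmed at each end), upper-quartile scaling, quantile normalization, the 50 most abundant genes left out, a 1.5-fold threshold, an exact binomial test of the reads with Benjamini-Hochberg adjustment at 0.05, unmatched random lists, and the mean of list members. For genes ordered by pressure the binomial test compared the control with -200 mmHg. Coding genes, genes of at least 200 nt, removal of the trend of the change with exon length (50 bins) and the 4 pressures alone were added after the data were seen. Filters on the mean, biotype or length leave a gene's own change as it was, and a pseudocount cannot turn its direction at a pressure. The trimmed mean shifts all genes of a library alike, so it repeats the reported list percentiles. The settings are therefore not independent checks.

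The functions were tested on simulated reads for 11911 genes, with 200 genes changed. Reads were drawn at the mean rates of the 4 pressure libraries and the real library totals, so genes read mainly in the control were drawn near 0 reads. For each pressure against the control the size rule called 97.5% to 98.0% of genes changed 3-fold and 98.5% to 99.0% of genes changed 4-fold, and 0.307% to 0.427% of unchanged genes. These draws hold counting error and no variation between cultures. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.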

Results

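Mouse bone marrow mesenchymal stem cells (BMSCs), the adherent stromal cells of marrow that can form bone, fat and cartilage cells in culture, were profiled by RNA-seq after continuous negative pressure. The pressures were -80, -120, -160 and -200 mmHg for 48 h, and a culture at 0 mmHg was the control. Each of the 5 conditions had 1 library, so no difference between conditions has a replicate check, no p-value across genes is given, and intervals below cover the counting of reads only. The deposited FPKM values (fragments per kilobase of exon, scaled to the library total) gave back whole reads for 98.8% of 55401 genes. By that route the library totals were 18398911 reads in the control, 16638646 at -80 mmHg, 16600622 at -120 mmHg, 17012586 at -160 mmHg and 18056998 at -200 mmHg. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values, and a gene passed the size rule when it differed at least 2-fold with a mean of at least 1 FPKM.

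The first question was how gene expression under each pressure differed from the control. Every such change is measured against the same 1 control library. That library held 2525 reads of 5 Y-linked genes that had 0 reads in the pressure libraries, as described below. A different origin of the control cells and an effect of pressure therefore cannot be told apart. The words rose and fell describe the difference from that library only. Angptl7, a secreted angiopoietin-like protein, rose from 2.04 FPKM to between 210 and 260 FPKM. Scg2, a secretogranin of secretory granules, rose from 0.108 FPKM to between 77.2 and 93.9 FPKM. Inhbb, which encodes an activin and inhibin subunit, rose from 0.153 FPKM to between 15.8 and 19.3 FPKM, and Gas6, a ligand of TAM receptor kinases, from 9.41 FPKM to between 111 and 129 FPKM. In the other direction Sfrp1, a secreted Wnt antagonist, fell from 126 FPKM to between 0.139 and 0.282 FPKM. Mmp2, a gelatinase, fell from 398 FPKM to between 2.43 and 3.33 FPKM.

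In total 1292 genes were higher and 835 lower at -80 mmHg than in the control, 1072 and 781 at -120 mmHg, 1162 and 731 at -160 mmHg, and 1102 and 773 at -200 mmHg, of 12113 genes. Other large decreases were in Apod, a lipocalin (85.2 FPKM in the control, 1.01 to 1.60 under pressure), and Aspn, a small leucine-rich proteoglycan (33.8 FPKM, 0.0255 to 0.150). Prss22, a serine protease, rose from 0.862 FPKM to between 33.9 and 45.4 FPKM, and Clca3a2 from 0.0957 FPKM to between 17.7 and 22.6 FPKM. The reads of Angptl7 at -200 mmHg were 121 times those of the control per library total (95% Clopper-Pearson interval 96.9 to 152), and those of Scg2, with 5 reads in the control, 869 times (372 to 2677). The median of all genes was itself 0.14 to 0.16 above the control on the log2 scale. With the trimmed mean of log ratios set to 0 the split at -200 mmHg became 784 higher and 1008 lower, and with a pseudocount of 5 it became 276 higher and 416 lower.

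**Figure D1:**
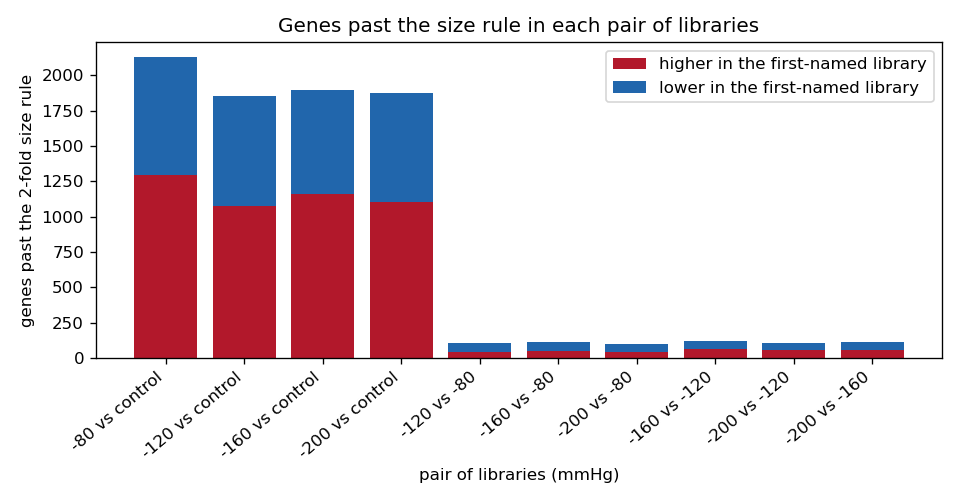
Number of genes past the 2-fold size rule (vertical axis) in each of the 10 pairs of the 5 libraries (horizontal axis), split into genes higher and lower in the first-named library. The 4 pairs with the control hold 1853 to 2127 genes and the 6 pairs of pressures 100 to 118.

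Osteogenic markers did not stand apart as a group, but this depended on filter and scaling, in opposite directions. Under quantile normalization their list lay above at all 4 pressures (mean of the 4 medians 0.42), with a mean of at least 5 FPKM it lay at the 96.7 to 99.1 percentiles, and with no filter at the 0.67 to 4.34 percentiles. Of 30 genes on the list 17 were measured, 0 of these were higher and 3 lower at all 4 pressures, and 10 passed the size rule at no pressure. At -80, -120, -160 and -200 mmHg in turn 0, 0, 0 and 1 were higher and 5, 3, 6 and 5 lower. Spp1 (osteopontin), a bone matrix phosphoprotein, fell from 1750 FPKM to between 81.7 and 117 FPKM, Postn (periostin) from 16.8 FPKM to between 0.104 and 0.173 FPKM, and Omd (osteomodulin) from 4.95 FPKM to between 0.739 and 0.935 FPKM. Runx2, the transcription factor needed for osteoblast formation, stood at 3.49 FPKM in the control and 5.79 to 6.90 FPKM under pressure, below the size rule. Col1a1, the main collagen of bone, stood at 930 FPKM in the control and passed the rule only at -160 mmHg (455 FPKM) and -200 mmHg (435 FPKM). Alpl (alkaline phosphatase) stood at 3.03 FPKM and 0.894 to 1.28 FPKM, with 225 reads in the control. Sp7 and Bglap (osteocalcin) were at or under 8 reads in every library, and Ibsp had 0 reads in all 5, so their change was not detectable at this depth. The median log2 change of the list lay between -0.05 and 0.07, while its mean lay between -0.53 and -0.46. The median lay at the 34.7 to 58.6 percentiles of random lists matched on expression, and it differed in sign from the mean at -120 mmHg.

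**Figure D2:**
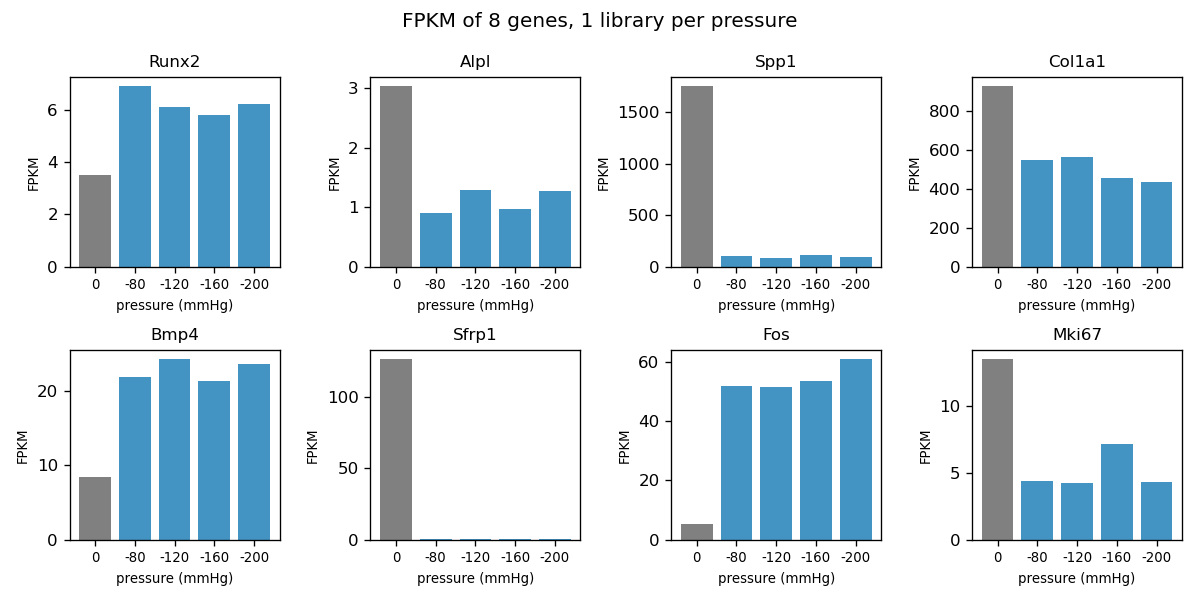
FPKM (vertical axes, starting at 0) of 8 genes against pressure in mmHg (horizontal axes), 1 bar per library with the control in grey and no replicates. Spp1 falls from 1750 FPKM to at most 117 FPKM, whereas Fos rises from 5.13 FPKM to at least 51.3 FPKM.

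Of 31 measured members of the bone morphogenetic protein (BMP) and TGF-beta pathway 6 were higher and 2 lower at all 4 pressures and 20 passed the rule at no pressure, and the list's median log2 change of 0.41 to 0.63 lay between the 97.9 and 100 percentiles of random lists. Bmp4, an osteoinductive ligand, rose from 8.44 FPKM to between 21.3 and 24.3 FPKM. Grem1, a secreted BMP antagonist, rose from 41.2 FPKM to between 164 and 176 FPKM, and Tgfbr2, the type II TGF-beta receptor, from 24.5 FPKM to between 61.6 and 69.7 FPKM. Tgfbi, a TGF-beta induced matrix protein, fell from 43.8 FPKM to between 2.18 and 2.79 FPKM. Bmp2 had 24 reads in the control and 0 reads in every pressure library, at least 7.22-fold lower against a floor of 3 reads per library. In the Wnt list, 5 of 21 measured members were higher and 3 lower at all 4 pressures. Axin2, a feedback target of Wnt signalling, rose from 0.395 FPKM to between 3.70 and 4.04 FPKM, while the ligand gene Wnt10b fell from 8.20 FPKM to between 0.319 and 0.501 FPKM.

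Of 27 measured immediate early genes 11 were higher and 1 lower at all 4 pressures and 13 passed the rule at no pressure, with a median log2 change of 0.64 to 0.72 (mean of the 4 medians 0.68, and 1.40 over the 18 members at 5 FPKM). Fos rose from 5.13 FPKM to between 51.3 and 60.8 FPKM, Btg2 from 2.54 FPKM to between 18.7 and 22.2 FPKM and the nuclear receptor gene Nr4a1 from 4.69 FPKM to between 21.4 and 27.9 FPKM, whereas Klf6 fell from 11.7 FPKM to between 0.589 and 0.959 FPKM. Among 23 measured mechanosensing channels and integrins 2 were higher and 2 lower at all 4 pressures, and 15 passed the rule at no pressure. Itga11, a collagen-binding integrin, rose from 1.95 FPKM to between 20.02 and 23.5 FPKM, and Cav1 (caveolin) fell from 141 FPKM to between 26.7 and 31.0 FPKM. The median of that list was 0.54 to 0.64, above the 99.8 percentile, but the list did not stand apart at all 4 pressures with no filter or with the length trend removed. The YAP/TAZ targets Ccn2 (19.3 FPKM to between 71.7 and 89.3 FPKM) and Ccn1 (131 FPKM to between 386 and 475 FPKM) rose as well, and their list stood apart at 3 of 4 pressures. That depended on the setting: the list did so at all 4 with a pseudocount of 0.1, with no filter, at 5 FPKM and with the 50 most abundant genes left out, and lay at the 79.05 to 98.45 percentiles under quantile normalization.

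Of 33 measured genes of the unfolded protein and integrated stress response 7 were higher and 0 lower at all 4 pressures and 25 passed the rule at no pressure, with a median of 0.49 to 0.59. Dnajc3, an endoplasmic reticulum co-chaperone, rose from 13.1 FPKM to between 48.6 and 55.5 FPKM, and Ern1, which encodes the stress sensor IRE1, from 1.41 FPKM to between 6.85 and 8.54 FPKM. Angiogenic factors had a median of 0.49 to 0.84, with 4 of 19 measured members higher and 3 lower at all 4 pressures. Vegfd rose from 54.1 FPKM to between 189 and 215 FPKM and Igf1 from 0.516 FPKM to between 7.04 and 7.95 FPKM, whereas Angpt1 fell from 9.61 FPKM to between 1.87 and 2.12 FPKM. With the mean of the members in place of the median, the BMP, mechanosensing and angiogenic lists no longer stood apart at all 4 pressures. The BMP list also lost this with unmatched random lists, with no filter and under quantile normalization, and the angiogenic list at 5 FPKM, under quantile normalization and with no filter (35.2 to 88.6 percentiles).

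Proliferation genes were lower under pressure. All 42 members were measured, 17 of them were lower and 0 higher at all 4 pressures, 10 passed the rule at no pressure, and the median log2 change was -1.33 at -80 mmHg, -1.32 at -120 mmHg, -0.91 at -160 mmHg and -1.29 at -200 mmHg. Mki67, the Ki-67 antigen of cycling cells, stood at 13.5 FPKM in the control, 4.37, 4.197 and 4.29 FPKM at -80, -120 and -200 mmHg, and 7.13 FPKM at -160 mmHg. Ccnb1, the mitotic cyclin B1, fell from 22.2 FPKM to between 4.15 and 7.15 FPKM, and Cdc45, a replication helicase factor, from 13.3 FPKM to between 1.82 and 3.84 FPKM. Of 49 cytosolic ribosomal protein genes 10 were lower and 0 higher at all 4 pressures and 25 passed the rule at no pressure, and of 32 nuclear genes of oxidative phosphorylation 5 were lower, 0 higher and 22 past it at no pressure. The medians of these lists were -0.99 to -0.75 and -0.63 to -0.59, and under quantile normalization the mean of the 4 ribosomal medians shrank from -0.89 to -0.36. Rps23 fell from 894 FPKM to between 261 and 290 FPKM, and Uqcrb, a subunit of respiratory complex III, from 102 FPKM to between 22.0 and 25.4 FPKM. Many ribosomal protein genes have pseudogenes that can share reads with them.

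Of 33 measured interferon response genes 16 were lower and 0 higher at all 4 pressures (median -1.33 to -1.03), and 13 passed the rule at no pressure. Of 26 inflammatory cytokines and NF-kB targets 6 were lower and 1 higher (median -0.75 to -0.66), and 15 passed it at no pressure. The higher member, named after its values were seen, was Il33 (log2 change 1.28 to 1.65). Counted at each pressure alone, 2 or 3 members were higher and 6 or 7 lower. Il6, also on this list and given further below, stood higher under pressure as well. Isg15, a ubiquitin-like interferon-induced protein, fell from 1051 FPKM to between 74.7 and 91.0 FPKM, and Oas2 from 53.2 FPKM to between 2.86 and 4.74 FPKM. The chemokine genes Cxcl5 (1820 FPKM to between 232 and 277 FPKM) and Cxcl10 (79.8 FPKM to between 6.08 and 9.34 FPKM) fell, as did Nos2, the inducible nitric oxide synthase (28.8 FPKM to between 0.692 and 1.03 FPKM). Of the 25 lists with at least 5 measured members, 10 stood apart at all 4 pressures, 5 above and 5 below.

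Other lists held large changes in both directions. In the extracellular matrix list, 4 of 36 measured members were higher and 7 lower at all 4 pressures. Thbs2 (thrombospondin 2) rose from 155 FPKM to between 1226 and 1288 FPKM, and Col6a3 fell from 25.9 FPKM to between 3.82 and 4.57 FPKM. Of the proteases, Adamts2, a procollagen peptidase, rose from 7.12 FPKM to between 50.7 and 66.0 FPKM and Mmp13 (collagenase 3) fell from 75.5 FPKM to between 2.14 and 2.92 FPKM. Hypoxia and glycolysis genes had medians of -0.43, -0.36 and -0.36 at -80, -120 and -200 mmHg, and -0.05 at -160 mmHg, where the list did not stand apart. Under quantile normalization it stood apart at no pressure (15.1 to 74.9 percentiles). Adm (adrenomedullin) fell from 65.0 FPKM to between 1.67 and 2.005 FPKM. In the adipogenic list Fabp4, a fatty acid carrier, fell from 21.9 FPKM to between 1.53 and 1.95 FPKM, while Pparg stood at 2.60 FPKM in the control and 2.28 to 2.67 FPKM under pressure. Lists for contractile genes, heat shock, NRF2, p53, cholesterol synthesis, stromal surface markers and mitochondrially encoded genes stood apart at 0 of 4 pressures, as did the extracellular matrix and adipogenic lists. With the length trend removed, an alternative added after the data were seen, the extracellular matrix list stood apart below at all 4 (mean of the 4 medians -0.48 in place of -0.19). The Wnt list stood apart above at -120 mmHg (98.6 percentile), the osteoclast-regulating list below at -120 mmHg (1.91 percentile), and the protease list below at -120 and -200 mmHg (0.77 and 0.92 percentiles). With no filter the osteoclast-regulating and protease lists stood apart below at all 4 pressures (0.15 to 1.56 and 0.18 to 1.78 percentiles), and at 5 FPKM the protease list lay at the 14.9 to 32.8 percentiles.

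**Figure D3:**
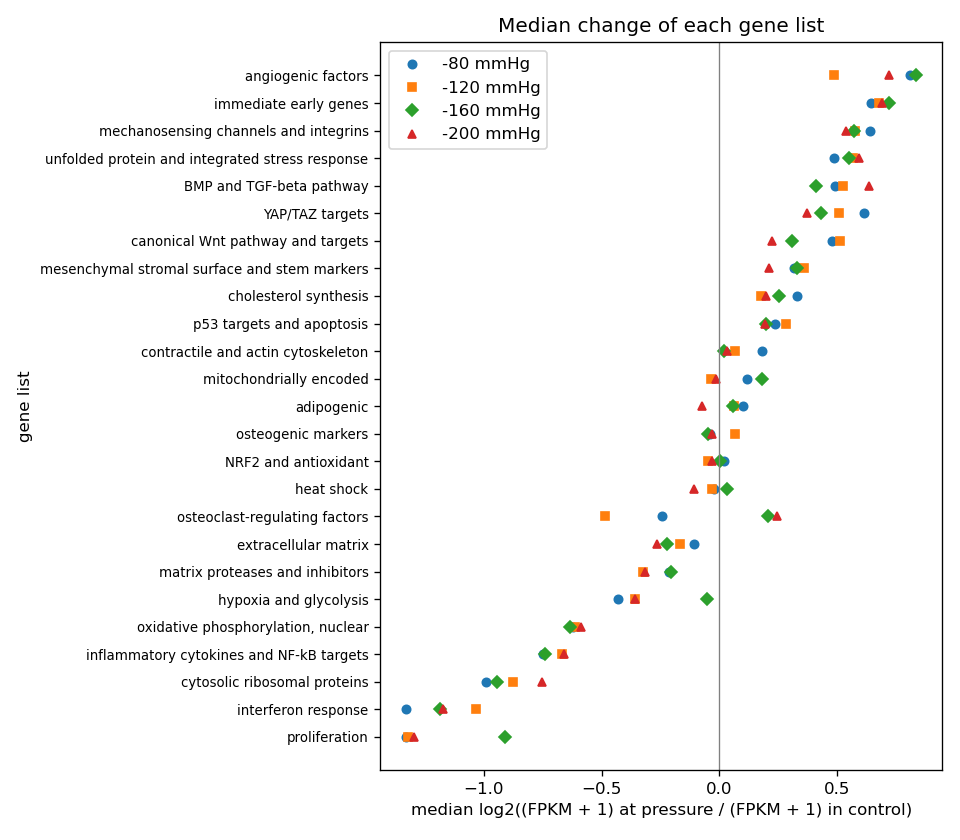
Median log2 ratio of FPKM + 1 at pressure to FPKM + 1 in the control (horizontal axis) of the 25 gene lists with at least 5 measured members (vertical axis), 1 symbol per pressure. Proliferation genes lie at -1.33 to -0.91 and immediate early genes at 0.64 to 0.72.

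Markers of other marrow and blood cells were mostly under the expression limit. Of 24 macrophage markers 4 were measured, with Lyz2 (1.57 FPKM to between 9.83 and 12.3 FPKM), Cd68 and Cd14 higher and Lgals3 lower at all 4 pressures. With the 50 most abundant genes left out, at least 5 were measured and the list stood apart above at all 4 pressures. Of 16 granulocyte markers 2 were measured, Prtn3 and Camp, both higher at all 4 pressures. Of 11 osteoclast markers 4 were measured, and Ctsk (78.1 FPKM to between 1.15 and 2.31 FPKM) and Mmp9 (11.99 FPKM to between 2.52 and 2.79 FPKM) fell. Plvap, an endothelial marker, rose from 0.711 FPKM to between 2.70 and 4.18 FPKM, and Ppbp, a platelet chemokine, fell from 5.72 FPKM to between 0.256 and 0.832 FPKM. Sox9 was the 1 measured member of the chondrogenic list, and it fell from 7.60 FPKM to between 2.10 and 3.02 FPKM. The lymphoid and skeletal muscle lists had 1 measured member each, which passed the rule at no pressure, and of 15 epithelial markers 0 were measured.

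The control library also differed from the 4 pressure libraries in genes that mark sex and body position. These genes were chosen after their values were seen. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty had 1089, 641, 445 and 318 reads in the control and 0 reads in every pressure library. Mid1-ps1, a pseudogene annotated on the Y chromosome from position 90753057, had 16 reads in the control and 11 to 28 under pressure. The genes named above lie elsewhere on that chromosome, between positions 897788 and 1286629. Of the 24 measured Hox genes, transcription factors of position along the body, 9 were higher and 1 lower at all 4 pressures, among them all 7 measured genes of the Hoxb cluster. Hoxb9 stood at 10.2 FPKM in the control and 54.6 to 59.8 FPKM under pressure, and Hoxc11 at 26.2 FPKM and 3.45 to 5.19 FPKM. H19, an imprinted noncoding RNA, had 1745 reads in the control and at most 2 reads in each pressure library. These differences run with every contrast against the control reported above, including each gene group.

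The next question was whether the pressures differed from one another. They were far closer to each other than to the control. The SD over genes of the log2 difference was 0.24 to 0.26 between pressures and 0.79 to 0.83 against the control, and Pearson's r across genes, which are not independent replicates, was 0.988 to 0.990 and 0.889 to 0.899. Between neighbouring pressures 107 genes (-120 against -80 mmHg), 118 genes (-160 against -120 mmHg) and 109 genes (-200 against -160 mmHg) passed the size rule. Of these 3, 3 and 4 were protein coding by the GENCODE annotation, and 80, 88 and 88 had exons of under 200 nt in all. Genes that stood apart in 1 pressure library rested on few reads, such as Snord93, a small nucleolar RNA gene, with 9 reads at -160 mmHg and at most 2 reads elsewhere. With an exact binomial test of the reads added, which compares the libraries and not the conditions, 27, 39 and 28 genes remained past the rule.

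In 1326 genes the control stood apart from all 4 pressure libraries by at least 2-fold. It was higher in 540 of them and lower, the side that the filter on the mean favours, in 786. Among the largest such genes were Sfrp1, Mmp2, H19 and Apod on the higher side and Scg2, Angptl7, Prss22, Clca3a2 and Mir196a-1, a microRNA precursor gene, on the lower side. Each other library stood apart in 9 to 12 genes. The exact permutation p over the 5 choices of the library apart was 0.2 (one-sided), the smallest that 5 libraries allow. The 4 comparisons share 1 control: simulated unchanged libraries gave on average 6.71 genes higher and 7.24 genes lower at all 4 pressures, and independent lists would give 0.998 and 0.207. The simulated libraries also shared 1 control, and it was drawn with each gene's SD among the 4 pressure libraries. A control culture that differs more than the pressure cultures differ among themselves is not in that draw. How much of the excess comes from such a control cannot be split.

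The last question was whether expression followed the strength of the pressure. Expression rose at every step from 0 to -200 mmHg, and by at least 2-fold in all, in 46 genes, and fell in the same way in 47 genes. The rising genes with the largest change were Clu (clusterin), from 6.85 to 66.5 FPKM, Mchr1, Aldh1a1, a retinaldehyde dehydrogenase (3.59 to 28.1 FPKM), Rarres2 (chemerin, 1.02 to 8.17 FPKM) and Ccn2. The falling genes were Mccc2, a subunit of a leucine-degrading carboxylase, from 9.10 FPKM to 0 reads at -200 mmHg, Ces1a, Lama4, a laminin chain (23.9 to 3.69 FPKM), Isyna1 and Cacna1g. Most of each change lay between the control and -80 mmHg, where Clu already stood at 50.2 FPKM and Lama4 at 3.91 FPKM. An exact permutation test over the 60 distinct orders of the libraries gave p = 0.233 (one-sided), since 14 orders held as many genes, and the highest other order held 236. All 14 start at the control, so this p mostly reflects the control standing apart: among the 24 orders that start there p was 0.583, and orders with the control inside held at most 9 genes. Over the 4 pressures alone, an alternative added after the data were seen, 21 genes were ordered and 8 of 12 orders held as many (exact permutation p = 0.667).

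**Figure D4:**
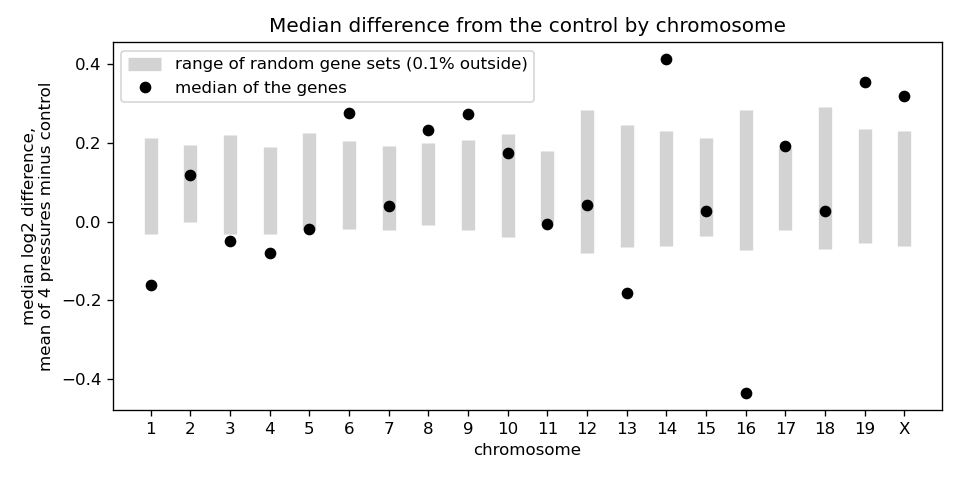
Median log2 difference, mean of the 4 pressures minus control (vertical axis), of the genes of each chromosome (horizontal axis), with grey bars for the range that 0.1% of 2000 random gene sets of the same size fall outside. The median is -0.44 on chromosome 16 and 0.41 on chromosome 14, and 13 of the 20 chromosomes lie outside the range.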

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

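The alternatives with coding genes only, with genes of at least 200 nt, with the length trend removed and with the 4 pressures alone were chosen after the data were seen. Between the control and each pressure (-80, -120, -160 and -200 mmHg in turn) a pseudocount of 5 gave 803, 704, 693 and 692 genes past the rule, a mean of at least 5 FPKM gave 1255, 1065, 1100 and 1049, and a 1.5-fold threshold gave 4928, 4377, 4630 and 4513, while a pseudocount of 0.1 gave 2868 at -160 mmHg. The smaller numbers at 5 FPKM come partly from fewer genes tested (7506), and for the other settings the cause was not tested. For the 3 neighbouring pairs (-120 against -80, -160 against -120, -200 against -160 mmHg) a pseudocount of 0.1 gave 216, 215 and 231 genes, a pseudocount of 5 gave 11, 12 and 10, no filter gave 278, 281 and 272, a mean of at least 5 FPKM gave 12, 16 and 20, and a 1.5-fold threshold gave 282, 299 and 300. The exact binomial test left 27, 39 and 28, coding genes only 3, 3 and 4, and genes of at least 200 nt 26, 30 and 19. The control stood apart in 2054 genes with a pseudocount of 0.1, 542 with a pseudocount of 5, 829 at 5 FPKM and 3414 at 1.5-fold. Genes ordered by pressure numbered 36 with a pseudocount of 5, 47 at 5 FPKM, 181 at 1.5-fold and 21 over the 4 pressures alone, and the exact permutation p ranged from 0.167 to 0.667 over all settings.

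The split of higher and lower genes moved with some settings and not with others. A pseudocount of 5 turned it (326 higher and 477 lower at -80 mmHg, 281 and 423 at -120 mmHg, 288 and 405 at -160 mmHg, 276 and 416 at -200 mmHg), while upper-quartile scaling left it near the reported one (1332 and 819 at -80 mmHg, 1061 and 785 at -120 mmHg, 1168 and 731 at -160 mmHg, 1143 and 749 at -200 mmHg, with medians of all genes of 0.14 to 0.17). With the trimmed mean set to 0 the split was 900 higher and 1126 lower at -80 mmHg, 770 and 998 at -120 mmHg, 805 and 1001 at -160 mmHg, and 784 and 1008 at -200 mmHg. With quantile normalization it was 812 and 903, 695 and 832, 713 and 824, and 696 and 848, and with the length trend removed 900 and 923, 820 and 838, 833 and 811, and 809 and 850. Lists were run in 13 partly redundant settings with the median, the reported one and unmatched random lists included. The proliferation, interferon, inflammatory, ribosomal, oxidative phosphorylation, immediate early and unfolded protein response lists stood apart at all 4 pressures in each. The BMP list did so in 10, the mechanosensing list in 11 and the angiogenic list in 10. With unmatched random lists the BMP list no longer did so, and the protease list stood apart below at all 4 pressures, as it did with the mean of the members and with no filter. The osteoclast-regulating list did so with no filter (mean of 4 medians -0.40 in place of -0.07) and the extracellular matrix list with the length trend removed. At 5 FPKM the immediate early list's mean of 4 medians was 1.40 in place of 0.68. A pseudocount of 5 lowered the mechanosensing list's from 0.58 to 0.33 and the angiogenic list's from 0.71 to 0.43. The osteogenic list's mean of 4 medians ranged from -0.16 to 0.42, and it stood apart, above, at all 4 pressures in 1 setting, quantile normalization. It lay at the 96.7 to 99.1 percentiles at 5 FPKM and at the 0.67 to 4.34 percentiles with no filter. Named genes past the rule on average, mostly picked for size, kept their direction in all 1398 values, which filters cannot change. Of these 1336 stayed past it. The binomial test and the 1.5-fold threshold give no value for list medians and single genes. Depth limits genes such as Sp7, Bglap and Ibsp, at or under 8 reads.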

Other observations

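The stromal and angiogenic gene groups held opposed changes within 1 list. Ly6a (Sca-1), a surface marker of mouse stromal cells, stood at 1740 FPKM in the control and 622 to 828 FPKM under pressure, while Thy1 (CD90) had 1 read in the control and 51 to 91 reads under pressure. Vim (vimentin), the intermediate filament of mesenchymal cells and a member of the contractile list, fell from 940 FPKM to between 210 and 235 FPKM. Ptn (pleiotrophin) fell from 49.7 FPKM to between 0.807 and 1.12 FPKM, and Vegfa stood at 36.9 FPKM in the control and 70.6 to 81.5 FPKM under pressure. Of the osteoclast-regulating factors, Il6 stood at 3.65 FPKM in the control and 7.62 to 11.1 FPKM under pressure, and Tnfsf11 (RANKL) at 1.87 FPKM and 1.05 to 2.40 FPKM.

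For the patterns below, the tests of scaling, gene length, read number, Y-linked genes and pressure itself were chosen after the results were seen, while those of chromosome parts, redrawn reads between pressures and redrawn proliferation reads were written before their results were seen. The control stood apart in 1326 genes, and the values argue against scaling between libraries (1061 genes after quantile normalization), the length trend (1186 genes after its removal) and few reads (829 genes among those with a mean of at least 5 FPKM, although 542 with a pseudocount of 5) as the whole cause. A candidate explanation is that the control cells came from another animal, line or passage than the pressure cells. The 5 Y-linked genes with at least 30 reads in the control had 2525 reads there and 0 in the 4 pressure libraries together, at least 759-fold lower (a cut chosen after the values were seen, which leaves out 3 pseudogenes, among them Mid1-ps1, with 16 reads in the control and 11, 12, 28 and 22 under pressure, and Gm20775, with 0 and at most 4), and the proximal and distal parts of the chromosomes shifted together over 20 chromosomes (Pearson's r = 0.787, permutation p = 4.00e-05, one-sided; Spearman's rho = 0.785, permutation p = 5.00e-05; r = 0.669 without the 2 chromosomes farthest from the median). That correlation is not specific: 2 of the 6 pairs of pressures also passed after adjustment over 7 contrasts (adjusted permutation p = 0.0243 and 0.00822), and up to 7 chromosomes lay outside the range of random gene sets in a pair of pressures against 13 here, although the chromosome medians of those pairs spread by an SD of at most 0.034 against 0.21 here. For those 5 Y-linked genes the values argue against pressure acting on the same cells. Whether pressure also changed the other genes stays open. With 1 library without pressure any difference of that culture, another origin of its cells included, is confounded with pressure and the 2 cannot be told apart.

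Between neighbouring pressures most genes past the rule were short and had few reads. Among genes with recovered reads 331 passed over the 3 pairs, and reads redrawn from the common mean of the 4 pressure libraries gave 136 on average and at most 159 in 100 draws, 41.0% of the observed number. For these genes as a set the values argue against the counting of independent reads as the whole cause, while part of the number may still come from it. The redraw holds no differences between cultures and no reads copied from 1 molecule. It therefore says nothing about where the rest comes from. No biological explanation was tested, since each pressure has 1 library.

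Proliferation genes lay nearer the control at -160 mmHg than at the other pressures. Of 42 members 41 were highest at -160 mmHg among the pressures, a pattern seen before it was tested, while redrawn reads gave 10.5 on average and 0% of 10000 draws reached it. The highest draw held 23 such members, so the values argue against the counting of independent reads as the whole cause. The redraw sets a single culture against counting error alone, so it says nothing about pressure. The median log2 difference of the members at -160 mmHg from the mean of the 3 other pressures was 0.38. Whether this came from the pressure of -160 mmHg itself or from another difference of that single culture cannot be told apart, because the pressure has 1 library.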
